A study of Homo sapiens with 24 samples.

How the data were processed

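Polyadenylated RNA of 24 cultures of SK-HEP-1 CRISPRi lines was sequenced from stranded TruSeq mRNA libraries, per the labels' protocols. The deposited table holds estimated counts per gene from RSEM, which need not be whole because reads that match more than 1 gene are split. The tools named in the submitters' processing notes are cutadapt, STAR, RSEM and DESeq2, with hg38 as the genome, and their versions are not given in the sources used here. Whether the counting used the strand is not given either, so values of genes that overlap others or lie antisense to them, and of near-identical copies, are uncertain. Between 5.6% and 7.16% of the values of a library were not whole. The series also describes long-read and HepG2 data, which were not analysed here.

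Each of the 24 columns was matched to its sample by the label in its name. The 45 rows for the second copy of the pseudoautosomal genes, with 0.0222% of all counts, were added to the matching X rows, which left 58825 genes. Counts were then rounded to whole numbers. Gene coordinates came from GENCODE release 29 on hg38, in which 47420 IDs were found with their version and 58552 without it; 147 symbols belong to more than 1 ID. With library totals of 66.4 M to 92.1 M, a level of 1 CPM stands for about 66.4 to 92.1 counts, so counting error weighs mainly on genes below 1 CPM, and it does not include the spread between cultures.

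Counts were normalised with TMM in edgeR 4.0.16 (R 4.3.3) after the filterByExpr filter with a minimum count of 10, and tested with edgeR's robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and called at 0.05. The response to Nutlin-3a was tested in 1 model of the 12 group means over all 24 libraries, which leaves 12 residual degrees of freedom, as the mean of the NTC lines and as the mean of the PURPL lines. Guides were assigned to lines, so PURPL lines were compared with NTC lines on the sum of the 2 harvests of each line, 4 lines against 2 within a treatment. The difference of responses was tested on the 12 sums with a term for each line. P-values of the Nutlin-3a responses therefore measure the spread between harvests of a line, and those of the guide comparisons the spread between lines. An exact permutation test over the 15 splits of the 6 lines was run for PURPL. Single guides against the NTC mean, and all pairs of lines, were tested in the model of 12 group means, and correlations between guides were set beside those of 10 simulated sets of unchanged guides.

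Fixed gene lists, 16 in number, and 6 lists of cell type or RNA quality markers were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and adjusted over the 16 lists or the 6 marker lists of each comparison. The lists covered p53 targets of growth arrest, apoptosis, repair and metabolism and noncoding RNA, mitosis, G1/S and replication, unfolded protein and ATF4 stress, heat shock, interferon, NF-kB, matrix and TGF-beta, cholesterol synthesis, hypoxia and glycolysis, immediate early genes, ribosome biogenesis with MYBBP1A partners, and the neighbours of PURPL. Markers covered endothelial, hepatocyte, epithelial, fibroblast and mural, and leukocyte cells and nuclear-retained and mitochondrial RNA. ATF3, ACTA2, NEAT1 and PURPL are examples of genes in more than 1 list. Camera with an estimated correlation and fry were the alternatives.

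The groups, tests, lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. For each comparison except Nutlin-3a in the PURPL lines, the rule named the 8 genes up and the 8 down with the largest log2 fold change among those called. They had to reach 1 CPM in the higher group and have the same direction in every pair. For every comparison it also named up to 4 members of each list by p, and PURPL, MDM2, CDKN1A, MYBBP1A and ELAVL1. Some genes that the rule names are not reported here. Where fewer than 5 genes passed, the 3 smallest p-values in each direction were named as not past the threshold. CXCL1 and CXCL2 were named by the rule in both guide comparisons, as list members with a small p. They were grouped with CXCL8 after their values were seen. CXCL3, IL6 and CDH10 in the guide comparisons, and other genes called by DESeq2 alone, were named after their values were seen.

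Alternatives were RLE size factors, no filter, a filter at 1 CPM, DESeq2 1.42.0, a minimum fold of 2, a block for the harvest number or pair, fewer or summed libraries, and each library, line or harvest left out. After the data were seen, fits without the divergent library, with the lowess trend of each library on transcript GC content removed, with both, and without harvest 3 of NTC1 in DMSO were added. GC content was known for 16327 of 16371 genes (99.7%). Each test was checked on simulated counts with 200 changed genes, where the Nutlin-3a tests recovered 46.3% of 2-fold and 86.4% of 4-fold changes in the NTC lines and 77.6% and 93.9% in the PURPL lines. The simulated libraries were drawn independently with the fitted spread and had no GC trends, so these shares may be higher than in the real data.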

Results

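RNA sequencing measured polyadenylated transcripts in 24 libraries of CRISPR interference (CRISPRi) lines of SK-HEP-1, an established human line from a liver tumour that the labels class as endothelial cells. In CRISPRi a catalytically inactive Cas9 carrying a repressor is directed to a promoter by a guide RNA. The lines carried 1 of 2 non-targeting guides (NTC1 and NTC2) or 1 of 4 guides against PURPL (sg2, sg4, sg5 and sg6), a long noncoding RNA known to be induced by p53. Each of the 6 lines was given Nutlin-3a at 10 µM or its vehicle DMSO for 6 h. Nutlin-3a blocks the binding of MDM2 to p53 and so stabilises p53. Every one of the 12 combinations of line and treatment had 2 harvests, numbered 1 and 3, which the labels call biological replicates. Estimated counts per library summed to between 66.4 M and 92.1 M, with a median of 74.2 M. Levels are given as CPM, counts scaled to the library total after TMM normalisation, as mean ± SD.

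Of 18 endothelial, 20 hepatocyte and 11 leukocyte markers, 9, 3 and 4 passed the expression filter of the Nutlin-3a comparisons. Vimentin (VIM) lay between 3570 and 4870 CPM, whereas PECAM1 reached at most 0.0277 CPM, CDH5 0.0591 CPM, albumin (ALB) 0.0142 CPM and PTPRC 0.13 CPM over the 24 libraries. AFP lay between 0.836 and 1.62 CPM, EPCAM between 0.295 and 0.761 CPM and COL1A1 between 0.309 and 6.31 CPM. Libraries of the same treatment resembled each other, with a median Pearson r across genes of 0.987 to 0.995, except the sg2 library with Nutlin-3a from harvest 1, at 0.907. In that library log2 levels relative to the median library rose by 1.47 for each 10 percentage points of transcript GC content, against slopes of -0.205 to 0.329 in the other 23 libraries. It is called the divergent library below. The GC slope also differed within groups among the other libraries, for example 0.104 and 0.294 in the harvests of NTC1 with DMSO and -0.023 and 0.329 in those of sg5 with Nutlin-3a.

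**Figure D1:**
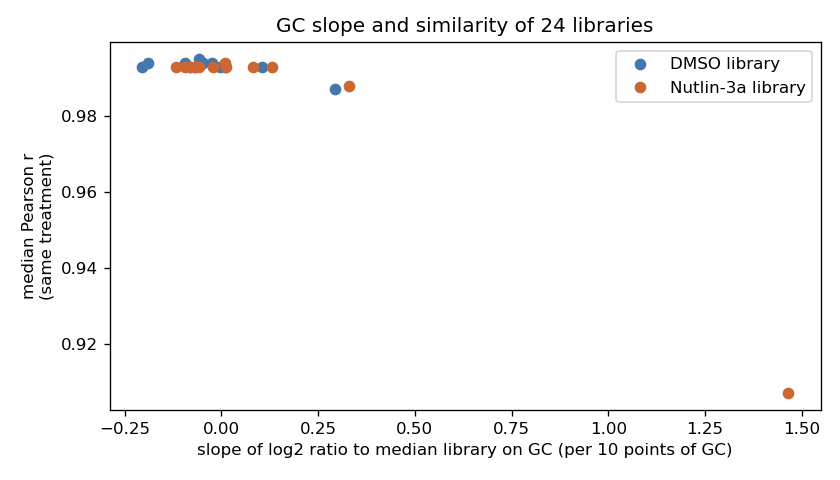
GC slope (log2 per 10 points of transcript GC content, x axis) against the median Pearson r with libraries of the same treatment (y axis) for the 24 libraries, 1 point each. The divergent library, at a slope of 1.47 and r = 0.907, lies apart from the other 23.

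The first question was whether the guides lowered PURPL. PURPL (ENSG00000250337.6, lincRNA, hg38 chromosome 5, 27472292 to 27496401, plus strand) was far lower in every PURPL guide line than in both NTC lines, with either treatment. In DMSO it stood at 7.44 ± 0.0485 CPM in NTC1 and 9.27 ± 1.16 CPM in NTC2 (n = 2 harvests each). The guide lines had 0.30 ± 0.0371 CPM (sg2), 0.52 ± 0.00401 CPM (sg4), 0.827 ± 0.0579 CPM (sg5) and 0.578 ± 0.0593 CPM (sg6). These levels were 3.59%, 6.23%, 9.9% and 6.92% of the NTC mean. With Nutlin-3a, NTC1 reached 34.1 ± 6.21 CPM and NTC2 31.2 ± 1.22 CPM. There sg2 had 1.08 ± 0.479 CPM, sg4 2.15 ± 0.402 CPM, sg5 2.50 ± 0.578 CPM and sg6 1.62 ± 0.0394 CPM, or 3.31%, 6.58%, 7.63% and 4.95% of the NTC mean. PURPL counts per library ranged from 22 to 205 in the guide lines and from 565 to 2843 in the NTC lines. Nutlin-3a raised the residual PURPL in the guide lines by 2.79-fold to 4.13-fold, and PURPL in NTC1 and NTC2 by 4.62-fold and 3.37-fold.

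With the 6 lines as replicates, PURPL fell by 3.92 on the log2 scale in DMSO (SE 0.29, edgeR adjusted p = 0.0127). In Nutlin-3a the log2 difference was -4.16 (SE 0.34), which did not pass (edgeR adjusted p = 0.432). With the divergent library left out it was -4.06 (SE 0.17, edgeR adjusted p = 4.89e-05). Over all alternatives the adjusted p ranged from 2.8e-24 to 0.933. The NTC lines were the 2 highest of the 6 lines in both treatments, and the exact two-sided permutation p of 0.0667 is the smallest that the 15 splits of 6 lines can give. In DMSO the call was lost when sg4, sg6, NTC1 (which leaves 1 NTC line) or harvest 1 was left out, with log2 differences of -3.89 to -4.07.

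**Figure D2:**
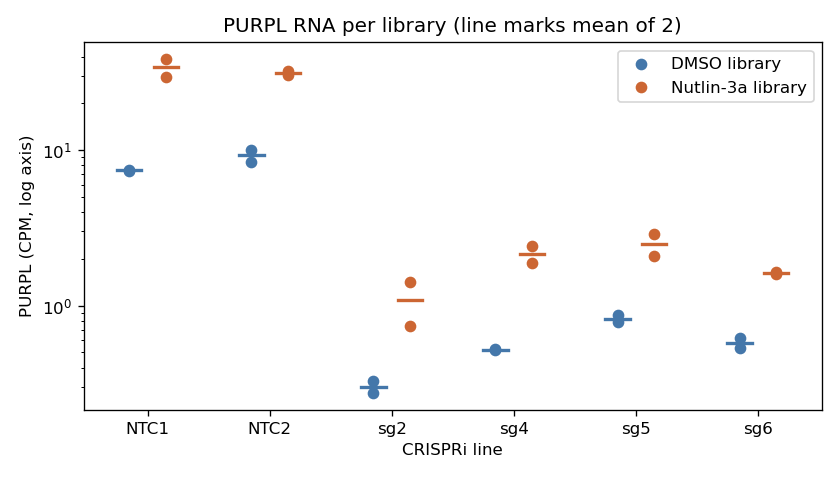
PURPL level (CPM, log axis) in each of the 24 libraries by CRISPRi line, with DMSO and Nutlin-3a libraries as separate colours and bars at the mean of 2 harvests. Every library of the 4 PURPL guide lines lies at or below 2.90 CPM, and every NTC library lies at or above 7.40 CPM.

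The second question was what p53 activation does in lines with normal PURPL. In the NTC lines Nutlin-3a raised the textbook p53 targets strongly. The CDK inhibitor CDKN1A (p21) went from 84.7 ± 17.6 to 1009 ± 67 CPM (n = 4 libraries per treatment), a log2 fold change of 3.59 (SE 0.23, edgeR adjusted p = 9.73e-08). MDM2, the ubiquitin ligase that degrades p53, went from 424.6 ± 45.2 to 3936 ± 259 CPM (3.22, SE 0.22, adjusted p = 2.67e-07). The antiproliferative gene BTG2 rose from 16.0 ± 1.83 to 184.7 ± 10.3 CPM (3.53, SE 0.10, adjusted p = 1.64e-11), and PURPL itself from 8.35 ± 1.25 to 32.7 ± 4.02 CPM (1.98, SE 0.18, adjusted p = 3.15e-06). MYBBP1A, a nucleolar protein, had -0.45 (SE 0.39) and the RNA-binding protein ELAVL1 (HuR) -0.18 (SE 0.08), neither past the threshold.

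By fold, the genes that rose most in the NTC lines were GRIN2C, an NMDA receptor subunit (4.72, SE 0.47, from 0.139 to 3.66 CPM), and SLC52A1, a riboflavin transporter (4.71, SE 0.62, from 0.0367 to 1.02 CPM). Behind them came the adhesion gene NECTIN4 (4.09, SE 0.22), WDR63 (4.02, SE 0.22), the pseudogene NBEAP1 (3.98, SE 0.27) and the lincRNA AL109976.1 (3.94, SE 0.44). Among the genes that fell most, E2F2 dropped from 10.9 ± 1.59 to 1.66 ± 0.383 CPM (-2.71, SE 0.20), ZNF367 from 53.5 ± 8.12 to 10.1 ± 0.369 CPM (-2.40, SE 0.26) and cyclin E2 (CCNE2) from 85.6 ± 13.5 to 17.9 ± 0.346 CPM (-2.24, SE 0.29). FAM111B (-2.13, SE 0.26), the transcription factor MYB (-2.09, SE 0.19), the p53 relative TP73 (-1.79, SE 0.39), NXPH2 (-1.78, SE 0.26) and cyclin E1 (CCNE1; -1.71, SE 0.12) fell as well. Each of these 14 genes moved the same way in 4 of 4 pairs of harvests of the same line and number, as was required to name it here, with edgeR adjusted p of at most 0.00897.

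Of 16371 genes tested, 684 rose and 659 fell at an edgeR adjusted p under 0.05. Of these, 254 and 92 changed by at least 2-fold. The count depended on the libraries used. Without the divergent library, which is not among these lines but shares the estimate of the spread, 1482 rose and 2655 fell. Leaving out harvest 3 of NTC2 in DMSO, or harvest 1 or 3 of NTC1 or NTC2 with Nutlin-3a, gave 796, 895, 810, 824 and 847 calls in the order NTC2 DMSO 3, NTC1 1, NTC1 3, NTC2 1 and NTC2 3.

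The p53 target lists rose together in the NTC lines. Of 30 genes of growth arrest and p53 feedback, 24 rose and 0 fell (27 and 0 adjusted over the list alone), among them the stress sensor SESN1 (2.76, SE 0.16) and CYFIP2 (1.89, SE 0.08). Of 23 apoptosis genes, 15 rose and 0 fell (16 and 1 adjusted over the list alone), including the TRAIL receptors TNFRSF10B (1.17, SE 0.06), TNFRSF10A (1.06, SE 0.09) and TNFRSF10D (0.87, SE 0.09) and the F-box gene FBXO22 (1.09, SE 0.09). Of 28 genes of DNA repair and metabolism, 18 rose and 0 fell (21 and 0 adjusted over the list alone), led by the ceramidase ACER2 (3.13, SE 0.16), the translesion polymerase POLH (1.48, SE 0.08), the iron-sulfur scaffold ISCU (1.11, SE 0.08) and CMBL (1.55, SE 0.11). Of 14 tested members of the list of p53-linked long noncoding RNAs, 7 rose and 0 fell (9 and 0 adjusted over the list alone), among them PINCR (2.38, SE 0.38), NEAT1 (1.41, SE 0.22) and PVT1 (0.64, SE 0.10). That fixed list also names WRAP53, a protein-coding gene. The limma camera test placed all 4 lists above other genes, with adjusted p of 4.3e-05 or less with an estimated correlation.

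Cell cycle genes fell. Of 46 genes of the G1/S transition and DNA replication, 30 fell (36 adjusted over the list alone), with the origin recognition subunit ORC1 at -1.34 (SE 0.08) and the chromatin assembly subunit CHAF1B at -1.02 (SE 0.08). The 2 that rose were E2F7 (0.89, SE 0.16), a repressor of E2F targets, and PCNA (0.42, SE 0.10), both known p53 targets. Of 40 mitotic genes, 19 fell and 0 rose (27 and 0 adjusted over the list alone), by less: HJURP -0.95 (SE 0.09), CENPA -0.97 (SE 0.11), AURKA -0.68 (SE 0.10) and KIF2C -0.65 (SE 0.09). The camera adjusted p with an estimated correlation was 2.67e-05 for the G1/S list and 0.00853 for the mitotic list. In the fit without the divergent library 37 mitotic and 39 G1/S genes fell.

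Single members of other lists changed in the NTC lines without the list standing out once correlation was estimated. In the unfolded protein and ATF4 list 4 of 25 rose (4 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation): ATF3 (1.48, SE 0.23), SESN2 (1.64, SE 0.31), DDIT4 (2.01, SE 0.52) and the chaperone HSPA5 (0.44, SE 0.12). ATF3, SESN2 and DDIT4 are also known p53 targets. In the interferon list 4 of 23 rose (4 over the list alone; adjusted p = 0.272 with an estimated correlation), namely STAT2 (0.52, SE 0.10), IFIT2 (0.71, SE 0.16), OAS2 (0.65, SE 0.16) and IFIT3 (0.46, SE 0.13). In the NF-kB list 3 of 22 rose (4 over the list alone; adjusted p = 0.376 with an estimated correlation), with the cytokines IL1B from 26.6 ± 2.98 to 113.4 ± 7.90 CPM (2.09, SE 0.16) and IL1A (1.59, SE 0.16), and BIRC3 (0.63, SE 0.17). In the list of ribosome biogenesis and MYBBP1A partners 5 of 26 fell (5 over the list alone; adjusted p = 0.0873 with an estimated correlation), among them nucleolin (NCL; -0.33, SE 0.06), NOLC1 (-0.47, SE 0.06), NOP56 (-0.51, SE 0.08) and dyskerin (DKC1; -0.45, SE 0.09). Of these 26 genes, 11 fell and 1 rose (15 and 1 over the list alone) without the divergent library, where 6 unfolded protein genes rose, and 5 NF-kB genes rose and 1 fell.

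Of 22 immediate early genes 4 rose and 3 fell (5 and 3 over the list alone), with DUSP5 at 0.64 (SE 0.08) and MYC at -0.89 (SE 0.19, from 100.7 ± 6.48 to 54.4 ± 2.76 CPM). In the matrix list 2 of 33 rose (2 over the list alone), among them ACTA2 (1.08, SE 0.18). In the hypoxia and glycolysis list 3 rose and 2 fell of 26 (3 and 3 over the list alone), with SLC2A3 at 0.53 (SE 0.10) and ALDOC at -0.99 (SE 0.26). In the heat shock list 1 of 15 rose (1 over the list alone), HSPA4L (1.80, SE 0.19), and in the cholesterol list 0 of 23 passed in edgeR in either direction. Those 5 lists had camera adjusted p of 0.313 to 0.627 with the preset correlation, and the median and mean of the heat shock list (-0.02 and 0.06) and of the immediate early list (-0.02 and 0.03) differed in sign. Of 8 genes around PURPL on chromosome 5, 2 rose and 1 fell (2 and 1 over the list alone; adjusted p = 0.226 with an estimated correlation, median -0.09, mean 0.55): the cadherin CDH10 went from 3.13 ± 0.554 to 28.6 ± 2.36 CPM (3.20, SE 0.17), PURPL rose, and CDH18 fell (-0.66, SE 0.09). The matrix list had 5 up and 4 down without the divergent library, the cholesterol list 3 and 2, the hypoxia list 3 and 4, the heat shock list 1 and 2 and the chromosome 5 list 2 and 4.

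Markers of RNA quality moved with Nutlin-3a in the NTC lines. Of 12 nuclear-retained and mitochondrial transcripts 5 rose (10 over the list alone; adjusted p = 0.122 with an estimated correlation), NEAT1 and the mitochondrial MT-CO1 (0.55, SE 0.09), MT-CO2, MT-ND4 (0.61, SE 0.09) and MT-ND5. Mitochondrial transcripts made up 0.81% to 0.93% of counts in the NTC libraries with DMSO and 1.1% to 1.47% with Nutlin-3a. Of the other marker lists, 2 of 11 fibroblast and mural markers rose (2 over the list alone), 0 of 4 leukocyte markers passed (1 over the list alone), and 0 of 9 endothelial, 0 of 3 hepatocyte and 0 of 6 epithelial markers passed in edgeR, with camera adjusted p of 0.264 to 0.875.

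The same treatment in the 4 PURPL guide lines gave a similar set of changes. CDKN1A rose by 4.07 on the log2 scale (SE 0.16, from 86.1 ± 6.16 to 1485 ± 620 CPM, n = 8 libraries per treatment; 1272 CPM with the divergent library left out), MDM2 by 3.09 (SE 0.16), BTG2 by 3.55 (SE 0.07) and the residual PURPL by 1.74 (SE 0.14), with edgeR adjusted p of at most 2.25e-07. E2F2 fell by 2.70 (SE 0.14), CCNE2 by 2.63 (SE 0.21) and FAM111B by 2.64 (SE 0.19). ELAVL1 fell by 0.15 (SE 0.05, edgeR adjusted p = 0.0404), and MYBBP1A (0.39, SE 0.28, and -0.20 with the GC trend removed) did not pass. Of the p53 lists 29 of 30, 19 of 23, 25 of 28 and 11 of 14 members rose, in the order growth arrest, apoptosis, repair and metabolism, and noncoding RNA (29, 19, 25 and 11 adjusted over the list alone). Of the cell cycle lists 33 of 40 mitotic genes fell, and 35 of 46 G1/S genes fell while 3 rose (33 and 36 fell adjusted over the list alone). These 6 lists passed camera with an estimated correlation (adjusted p of 0.00234 or less).

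Of the remaining lists in the guide lines, 12 of 25 unfolded protein and ATF4 genes rose (adjusted p = 0.162 with an estimated correlation), 7 of 22 NF-kB genes rose (0.382 with an estimated correlation), and 11 of 26 ribosome biogenesis genes fell while 3 rose (0.222 with an estimated correlation). The preset correlation gave adjusted p of 4.16e-05, 0.00275 and 0.0134. The interferon list had 9 members up of 23 and 0 down, the matrix list 9 up and 4 down of 33, the cholesterol list 3 up and 2 down of 23, the hypoxia list 5 up and 5 down of 26, the immediate early list 5 up and 4 down of 22, the heat shock list 3 up and 2 down of 15 and the chromosome 5 list 2 up and 4 down of 8, with camera adjusted p of 0.0924 to 0.861. Adjusted over the list alone, these counts were 10 and 0, 11 and 5, 2 and 1, 8 and 5, 5 and 4, 3 and 2, and 2 and 4, and they were 14, 7, 11 and 3 for the unfolded protein (up), NF-kB (up) and ribosome biogenesis (down and up) lists. These counts depended on the divergent library. With it left out, the NF-kB list had 6 up and 2 down and its median went from 0.32 to -0.02, and the ribosome biogenesis list had 0 up and 14 down. The cholesterol list had 3 and 5, the heat shock list 3 and 5 and the hypoxia list 5 and 7 there. The heat shock and chromosome 5 lists had medians of -0.05 and -0.06 and means of 0.21 and 0.40. RNA quality transcripts rose in 6 of 12 cases (adjusted p = 0.0247 preset and 0.673 estimated). Fibroblast and mural markers rose in 3 of 11 cases, endothelial in 2 of 9, leukocyte in 3 of 4, hepatocyte in 1 of 3, and epithelial markers rose in 2 and fell in 1 of 6, with camera adjusted p of 0.0522 to 0.583.

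In the guide lines 2896 genes rose and 2707 fell of 16371 tested (edgeR adjusted p under 0.05), 929 and 172 of them by at least 2-fold. The balance depended on the fit: 1562 rose and 2558 fell on line sums, and 1414 and 2077 with only the lines compared. Of the 1343 genes called in the NTC lines, 652 rose and 647 fell in both sets of lines and 0 moved in opposite directions. Independent lists of these sizes would share 121 and 109, and the 2 sets share no library. For the 346 genes that changed at least 2-fold in the NTC lines, the median ratio of the log2 response in guide lines to that in NTC lines was 0.976. Over all genes tested the 2 responses had a Pearson r of 0.528. The share of NTC calls also called in the same direction in the guide lines was 96.7% with all libraries and 87.2% without the divergent library. With the GC trend also removed it was 88.4%, and 4 genes moved in opposite directions. The count in the guide lines was 11221 without the sg2 library with Nutlin-3a from harvest 3, which leaves the divergent library as the only one of its group.

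**Figure D3:**
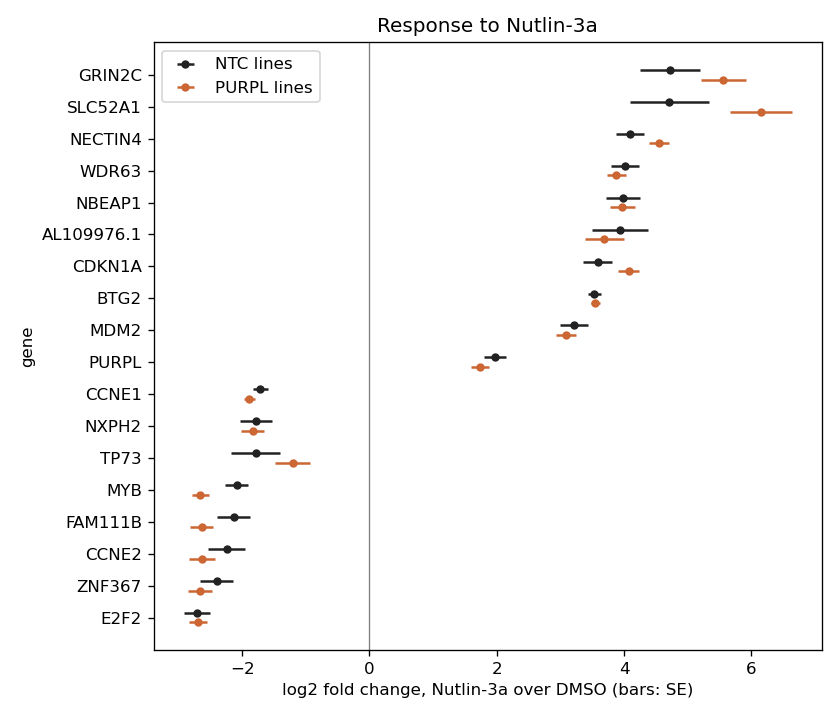
Log2 fold change of Nutlin-3a over DMSO (x axis, bars show the SE) for the genes that rose or fell most in the NTC lines and for MDM2 and PURPL, in the 2 NTC lines and in the 4 PURPL guide lines. Values of both sets have the same sign for every gene, with CDKN1A at 3.59 and 4.07.

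The third question was what lower PURPL does without p53 activation. In DMSO the PURPL transcript itself was the 1 gene of 16649 that passed in edgeR with the line as replicate. At an unadjusted p under 0.05 there were 526 genes, where 832 are expected by chance, and DESeq2 called 11. The other genes of the chromosome 5 list did not pass, with CDH10 at 0.14 and CDH18 at 0.19 on the log2 scale. The lower coordinate of CDH10 lies 2.99 Mb from that of PURPL, and CDH18 (19472951 to 20575873) lies farther off. MDM2 (0.09, SE 0.08; 426.7 ± 49 CPM in 2 NTC lines and 454.8 ± 12.1 CPM in 4 PURPL lines), CDKN1A (0.01, SE 0.11), MYBBP1A (-0.20, SE 0.13) and ELAVL1 (-0.04, SE 0.06) did not pass, each with an edgeR adjusted p of 0.825 or more. The smallest p among the other genes belonged to AC242842.3 (1.90, SE 0.21, edgeR adjusted p = 0.119), the mechanosensitive channel PIEZO2 (0.89, SE 0.13; 1.61 ± 0.109 against 3.00 ± 0.204 CPM) and the deiodinase DIO2 (1.01, SE 0.15) on the higher side, and to the processed pseudogene AL162151.2 (-3.19, SE 0.51), AGAP5 (-0.91, SE 0.18) and PLCD4 (-0.69, SE 0.15) on the lower side. DESeq2's 11 calls were PURPL, AL162151.2 and IL24, lower, and AC242842.3, PIEZO2, DIO2, LRRC7, SLITRK6, AC022400.3, NHS and LIMA1, higher.

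No list member other than PURPL passed in DMSO, over all genes or over its list alone. The camera test with the preset correlation set the unfolded protein and ATF4 list (median -0.13, led by PPP1R15A at -0.30 and TRIB3 at -0.23), the immediate early list (median -0.15, DUSP1 at -0.25) and the NF-kB list (median -0.16, CXCL8 at -0.81 and CXCL2 at -0.59) below other genes, and the interferon list (median 0.15, OAS2 at 0.79) and the cholesterol list (median 0.07, HMGCS1 at 0.25) above. With an estimated correlation the adjusted p were 0.316 for each of them except 0.488 for the NF-kB list. The ribosome biogenesis list (median -0.05), the mitotic list (median 0.05) and the RNA quality list (median 0.15) passed with the preset correlation too, with adjusted p of 0.316, 0.475 and 0.293 when the correlation was estimated, as did the noncoding RNA list and the chromosome 5 list, which hold PURPL itself (adjusted p = 0.316 and 0.475 with an estimated correlation). The growth arrest, apoptosis and repair lists of p53 targets had camera adjusted p of 0.359, 0.977 and 0.445 and medians of 0.05, 0.005 and -0.003, while their means were -0.02 each. The chromosome 5 list had a median of 0.05 and a mean of -0.47, and the matrix list -0.02 and 0.05. The G1/S, heat shock, matrix and hypoxia lists had camera adjusted p of 0.297, 0.445, 0.236 and 0.112, and the 5 cell type marker lists 0.0676 to 0.886. The number of calls was 0 without sg4, without sg6 or without harvest 1. It was 6328 without NTC2 and 8 without NTC1, but these fits hold 1 NTC line and take the spread from the PURPL lines alone.

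The fourth question was what lower PURPL does during p53 activation. With Nutlin-3a 0 of 16901 genes passed in edgeR, where 287 had an unadjusted p under 0.05 and 845 are expected by chance. DESeq2 called 4, PURPL and the chemokine CXCL8, lower, and BIVM-ERCC5 and U2AF1L5, higher. CXCL8 (IL-8, ENSG00000169429.11, chromosome 4, 73740506 to 73743716) stood at 5.88 ± 0.46 CPM in the 2 NTC lines and 2.97 ± 0.197 CPM in the 4 PURPL lines (-0.96, SE 0.14, edgeR adjusted p = 0.676), and passed with the GC trend removed and the divergent library left out (-0.91, edgeR adjusted p = 0.0239, with a range of 3.14e-06 to 0.999 over its alternatives). Its neighbours CXCL1 (-0.55, SE 0.15) and CXCL2 (-0.67, SE 0.33) did not pass. CDKN1A was 1018 ± 17.2 CPM in NTC lines and 1483 ± 395 CPM in PURPL lines (0.58, SE 0.26), MDM2 3950 ± 157 and 3834 ± 750 CPM (-0.02, SE 0.19), MYBBP1A 0.94 (SE 0.65) and ELAVL1 0.00 (SE 0.06), none past the threshold. CDKN1A was 0.31 (SE 0.10), MDM2 0.10 and MYBBP1A 0.17 (SE 0.12) without the divergent library. The matrix gene COL1A2 (1.89, SE 0.34; 0.0448 ± 0.0147 against 0.165 ± 0.0306 CPM), RBMS2P1 (1.15, SE 0.26) and AC016737.1 (-1.36, SE 0.28) had the next smallest p and did not pass. BIVM-ERCC5 had 0 counts in the NTC lines and 0.231 ± 0.103 CPM in the PURPL lines. It is a readthrough of BIVM and ERCC5, so its estimated counts depend on how shared reads were split, as do those of U2AF1L5, a near-identical copy of U2AF1.

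**Figure D4:**
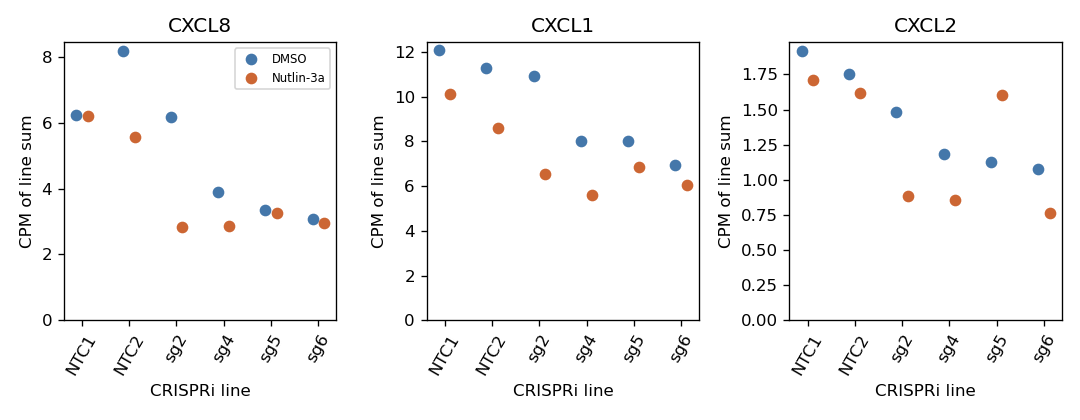
CPM of the line sums of CXCL8, CXCL1 and CXCL2 in each of the 6 lines with DMSO and with Nutlin-3a, 1 point per line and treatment and a separate linear axis from 0 for each gene. With Nutlin-3a, CXCL8 lies at 6.21 and 5.56 CPM in the NTC lines and at 2.82 to 3.25 CPM in the 4 PURPL lines, and CXCL2 in sg5 (1.60 CPM) lies close to the NTC lines (1.71 and 1.62 CPM).

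With the divergent library in the fit, camera's preset correlation put the mitotic list (median -0.17, MKI67 at -0.15), the G1/S list (median -0.06, mean 0.05) and the chromosome 5 list lower, and the matrix list (median 0.22, FBN1 at 0.48 and TAGLN at 0.57) and the cholesterol list (median 0.16, FDPS at 0.30) higher, and none held with an estimated correlation (adjusted p of 0.377 to 0.388). Adjusted over the list alone, PURPL passed as a member of 2 lists, and CXCL8 was the 1 NF-kB member to pass; in the noncoding RNA list, 2 of 14 members passed, lower. With the divergent library left out, the estimated correlation gave adjusted p of 0.0272 for the growth arrest list (median 0.10) and for the repair and metabolism list (median 0.08), 0.0265 for the matrix list (median 0.11) and 0.0203 for the cholesterol list (median 0.12), all higher in PURPL lines (and 0.0259 and 0.0203 for the noncoding RNA and chromosome 5 lists, lower, which hold PURPL), although 0 members of the 4 higher lists passed in edgeR over all genes. Adjusted over the list alone, 3 matrix genes, 3 fibroblast and mural markers and 1 apoptosis gene passed as higher in that fit, and 2 NF-kB genes as lower, besides PURPL. There the apoptosis list had 0.066 (median 0.04), the mitotic list 0.124 (median -0.09) and the NF-kB list 0.173 (median -0.02). The sum of sg2 held 1 library in that fit, and the lists were not tested with the GC trend removed. The other lists of p53 noncoding RNAs (0.234), unfolded protein (0.253), interferon (0.167), NF-kB (0.523), heat shock (0.533), hypoxia (0.172), immediate early (0.507) and ribosome biogenesis genes (0.454), and the growth arrest, apoptosis and repair lists of p53 targets (0.12, 0.376 and 0.108), did not pass camera with all libraries. Median and mean differed in sign there for the noncoding RNA (0.06 and -0.24), heat shock (-0.04 and 0.30), immediate early (-0.02 and 0.16) and ribosome biogenesis (-0.03 and 0.18) lists, and the NF-kB list tested lower with a median of 0.23.

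Marker lists also moved between the lines with Nutlin-3a. With all libraries, endothelial markers (median 0.735) and fibroblast and mural markers (median 0.75) were higher and RNA quality transcripts lower (median -0.12) in PURPL lines with the preset correlation, each with an adjusted p of 0.291 when it was estimated. Without the divergent library the fibroblast and mural median was smaller, at 0.44, and its adjusted p with an estimated correlation was 0.0246, and the endothelial list had 0.487 (median 0.385). The RNA quality list had a median of -0.066 there. Epithelial, leukocyte and hepatocyte markers had camera adjusted p of 0.26, 0.85 and 0.85. Some endothelial and fibroblast markers were low, such as VWF (median 0.0506 CPM over the 24 libraries) and COL1A1 (0.481 CPM). A change of cell type was not tested.

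The fifth question was whether the response to Nutlin-3a itself differs between PURPL and NTC lines. Of 17264 genes 0 passed in edgeR, where 621 had an unadjusted p under 0.05 and 863 are expected by chance, and DESeq2 called 2, AP001273.2 and AL162151.2. The difference of log2 responses was -0.27 (SE 0.23) for PURPL, 0.48 (SE 0.22) for CDKN1A, -0.16 (SE 0.21) for MDM2, 0.82 (SE 0.54) for MYBBP1A and 0.01 (SE 0.08) for ELAVL1, none past the threshold. It was 0.28 for CDKN1A, 0.006 for MDM2 and 0.33 (SE 0.16) for MYBBP1A without the divergent library. The smallest p belonged to AP001273.2 (2.21, SE 0.25), AL162151.2 (5.86, SE 0.68), AC009133.6, AC242842.3 (-2.04, SE 0.29), AC117503.2 (-1.70, SE 0.35) and AC022400.3 (-1.78, SE 0.42), each with an edgeR adjusted p of 0.533. AC009133.6 had 0 counts in the NTC lines with Nutlin-3a, 0.603 ± 0.853 CPM there with DMSO and 0.0666 ± 0.107 CPM in PURPL lines with Nutlin-3a, so no fold is given. AL162151.2 is a processed pseudogene, for which estimated counts are uncertain. Whether the other genes overlap further gene models, which would make their counts uncertain too, was not checked.

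Among the lists, the response of the mitotic genes was lower in PURPL lines (median -0.25, CENPE at -0.59 and MKI67 at -0.38), that of the unfolded protein and ATF4 genes higher (median 0.23, PHGDH at 0.81 and TRIB3 at 0.44), that of endothelial markers higher (median 0.80) and that of RNA quality transcripts lower (median -0.29) with the preset correlation. None held when it was estimated (adjusted p of 0.509, 0.485, 0.189 and 0.189). The medians were -0.16, 0.13, 0.37 and -0.23 without the divergent library, and the endothelial markers no longer passed with the preset correlation (adjusted p = 0.0524). The growth arrest, apoptosis, repair and noncoding p53 lists had camera adjusted p of 0.636, 0.636, 0.401 and 0.636, with medians of -0.01, -0.06, 0.09 and 0.05 and means of 0.21, 0.14, 0.19 and 0.09. Median and mean also differed in sign for the G1/S (-0.10 and 0.003), heat shock (-0.01 and 0.21), interferon (-0.15 and 0.07), cholesterol (-0.04 and 0.18) and ribosome biogenesis (-0.02 and 0.16) lists. The other lists had 0.0905 to 0.636 and the other marker lists 0.0826 to 0.587, and COL1A2 (1.98, SE 0.37) was the 1 member to pass adjusted over the list alone. Without the divergent library the growth arrest, apoptosis and repair lists each had a camera adjusted p of 0.559 with an estimated correlation. Their medians there were 0.02, 0.02 and 0.07. On simulated counts with known changes, the test of this difference recovered 57.6% of 4-fold and 23.9% of 2-fold changes, the comparison with Nutlin-3a 68.2% and 20.9%, and that in DMSO 87.9% and 76.1%. Simulated libraries were drawn independently with the fitted spread and no GC trend, so these shares may overstate detection in the real data. In the real data PURPL did not pass with Nutlin-3a at a log2 difference of -4.16 (edgeR adjusted p = 0.432).

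Single guides were set against the NTC mean, library by library. In DMSO 2, 1, 3 and 2 genes passed in edgeR for sg2, sg4, sg5 and sg6, and with Nutlin-3a 4067, 1, 2 and 2. The 2 NTC lines differed by 0 genes in either treatment. Without the divergent library the counts were 15, 1, 5 and 3 in DMSO and 2, 1, 8 and 3 with Nutlin-3a, and 2 and 3 between the NTC lines. There sg2 with Nutlin-3a held 1 library, so the other groups supplied the spread. Across genes, which are not independent replicates, the log2 fold changes of pairs of guides against the same controls had a mean r of 0.442 in DMSO and 0.44 with Nutlin-3a, where simulated unchanged guides gave 0.326 and 0.336. The covariance was 0.0341 and 0.0636 against a simulated 0.0439 and 0.0452. With 1 guide set against NTC1 and the other against NTC2, the covariance was -0.0147 in DMSO and 0.0462 with Nutlin-3a, and with the GC trend removed and the divergent library left out it was 2e-04 and 0.0067. The simulated 2e-04 and -1e-04 were near 0 by design, as libraries were drawn independently around 1 mean per treatment. The simulated sets held all 24 libraries, with a spread fitted with the divergent library and no GC trend removed. They therefore give no bound for these covariances.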

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

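The tests of the divergent library below were chosen after the result was seen, and the rule that reads all 6 pairs of lines, not their median alone, was set after the values of that test had been seen. The counts of the full comparisons with the GC trend removed had been seen before the tests on pairs of lines were written. Among 32 sets of libraries examined, 9 values stood far from the rest of their set. The nominal chance rate of the rule used is about 1 in 20 sets, which was not measured here, and the sets share libraries.

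The sg2 library with Nutlin-3a from harvest 1 accounts for 5 of these values. Its GC slope was 1.465 against -0.095 to 0.329 in the other libraries of PURPL lines with Nutlin-3a, its median r 0.907 against 0.988 to 0.993, its MDM2 1650 CPM against 3420 to 5140 CPM, CDKN1A 2970 CPM against 1090 to 1540 CPM and MYBBP1A 158 CPM against 20.7 to 41.8 CPM. An NTC or DMSO culture under a wrong label is argued against by its PURPL of 0.743 CPM, where NTC lines with Nutlin-3a had 29.7 CPM or more, and by CDKN1A at 2970 CPM, where DMSO libraries reached 110 CPM, and RNA from hepatocyte-like cells by a highest level of 4.08 CPM among ALB, APOA1 and SERPINA1. A GC bias may explain most of the departure, as GC content took up 69.9% of the variance of its log2 ratios, but with the trend removed their SD was still 0.772, down from 1.48, above the limit of 0.68 set at 1.5 times the highest SD of the other libraries (0.453), so what else differed stays open and no biological explanation was tested.

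In the other sets, harvest 3 of NTC1 with DMSO had a median r of 0.987 against 0.993 to 0.994 in the other NTC libraries with DMSO. MDM2 in harvest 1 of NTC2 with Nutlin-3a was 4320 CPM against 3770 to 3840 CPM. The GC slope of harvest 1 of sg6 with DMSO was -0.205 against -0.08 to 0.008. ELAVL1 in harvest 1 of sg5 with Nutlin-3a was 118 CPM against 136 to 141 CPM.

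More genes were called for Nutlin-3a in the 4 PURPL lines (5603) than in the 2 NTC lines (1343). If the number of libraries alone were responsible, pairs of PURPL lines should call about as many genes as the NTC pair, and their median was 2710.5, above the bound of 1.5 times the NTC count that had been written down beforehand. The 6 pairs ran from 1805 to 4919, and those without sg2 from 1805 to 1901, below that bound, so the number of libraries was neither excluded nor shown to be the source. With the GC trend removed and the divergent library left out, the pairs called a median of 5197.5 (4457 to 6146) and the NTC lines 5089, within that bound, but both counts rose and 2 choices changed at once. Leaving out the divergent library alone gave 4137 calls in the NTC and 6431 in the PURPL lines, which again compares 2 lines with 4. The median SE was 0.199 in the NTC and 0.141 in the PURPL contrast. On simulated counts these tests recovered 46.3% and 77.6% of 2-fold changes, so the PURPL contrast detects more changes of the same size. How much of the surplus this accounts for was not tested, and a part played by GC content stays open.

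CXCL8, CXCL1 and CXCL2, which encode chemokines that draw neutrophils, were lower in PURPL lines than in NTC lines with Nutlin-3a, with a median log2 fold change of -0.67, and none of the 3 passed in edgeR with all libraries. GC bias between the lines is argued against, since the median was -0.62 with the GC trend removed. The 3 genes were chosen as a set after their values were seen, so their rank among the 15 splits of the 6 lines (1 of 15, with a mean log2 difference of -0.77 and 0.59 as the highest other, and 2 of 15 with the GC trend removed) says nothing about chance. Of 2 related genes, IL6 overlapped between the lines with Nutlin-3a (3.96 and 3.74 CPM in the NTC lines, 3.97 in sg5), and CXCL3 was apart there but overlapped in DMSO (0.603 and 0.631 CPM, 0.731 in sg2). In DMSO sg2, the line with the least PURPL, lay close to the NTC lines. It had 6.16 CPM of CXCL8 against 6.23 and 8.17 CPM in the NTC lines, and 3.06 to 3.89 CPM in the other guide lines. CXCL1 was 10.9 CPM in sg2 against 12.1 and 11.3 CPM, and CXCL2 1.48 CPM against 1.92 and 1.75 CPM. With Nutlin-3a the sum of sg2 includes the divergent library. A lower chemokine level with less PURPL is a candidate explanation that the 2 NTC lines cannot separate from a difference of those lines.

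For the Nutlin-3a responses, splits of the libraries argue against chance. The real split of the 8 NTC libraries alone called 2528 genes and the highest of the other splits called 1, so 1 of 35 splits gave as many, the smallest share that they allow. The real split of the 16 PURPL libraries called 5357 genes, and 1 of 100 splits drawn gave as many. The highest other called 1317, kept 7 of the 8 DMSO libraries together and joined the divergent library to them. All other splits mix the treatments on both sides, which adds the treatment effect to the spread, and they do not take account of the line.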

How the results depend on the processing

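The GC fits and the fits without the divergent library or harvest 3 of NTC1 in DMSO were chosen after the data were seen. The cause was not tested unless the setting itself gives it, such as fewer libraries or a minimum fold. Calls for Nutlin-3a in the NTC lines (1343) were 824 with no low-count filter (60.9% higher against 50.9%), 346 at a fold of at least 2, 3651 with only the lines compared, 675 on line sums, 3786 with the GC trend removed, 4137 without the divergent library (35.8% higher), 5089 with both and 3545 without harvest 3 of NTC1 in DMSO and the divergent library; leaving out each library gave 796 to 1373. In the PURPL lines (5603) they were 1101 at a fold of at least 2, 3491 with only the lines compared (40.5% higher against 51.7%) and 3805 to 11221 with each library left out; without the divergent library 41.2% were higher. RLE size factors, the 1 CPM filter and DESeq2 kept both counts within 1.5 times. Harvest numbers were not used as pairs, but pairing stays open: deviations of same-numbered harvests correlated across genes at 0.019 to 0.324 between treatments, with a median of 0.143 within a line and 0.038 across lines. A block for the harvest number gave 1417 and 5421 calls in NTC and PURPL lines, a block for line and harvest pair 1284 and 4911, and that block with the GC trend removed 4739 and 8255.

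For PURPL against NTC lines in DMSO (1 call) DESeq2 gave 11, no filter, the GC trend removed, libraries as replicates and 12 group means of libraries 2 each, and leaving out each line or harvest 0 to 6328 (6328 and 8 with 1 NTC line left). With Nutlin-3a (0 calls in edgeR, 287 at an unadjusted p under 0.05, DESeq2 4) there was 1 call with the GC trend removed, without the divergent library, with libraries as replicates (also with the harvest block or without the divergent library), with limma voom and with both treatments in 1 model; 2 with the GC trend removed and the divergent library left out and with 12 group means of libraries; 3 with those means without the divergent library (ABCC2 with such means in each case, and IL7R, besides PURPL); and 0 to 1 with each line or harvest left out. The difference of responses (0 calls in edgeR, 621 at an unadjusted p under 0.05) had 2 with DESeq2, 1 with the GC trend removed and the divergent library left out, and 0 to 1 with each line or harvest left out.

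PURPL was lower in PURPL lines under every alternative run. In DMSO its log2 difference ranged from -4.17 to -3.71 with each line or harvest left out, and the call was lost at -4.07, -3.89, -3.93 and -3.92 without NTC1, sg4, sg6 and harvest 1. With Nutlin-3a it passed with DESeq2 (-4.15), the GC trend removed (-4.02), the divergent library left out (-4.06), both (-4.01), libraries as replicates (-4.14; -4.14 with the harvest block, -4.03 without the divergent library), limma voom (-4.23), 12 group means (-4.22; -4.11 without the divergent library) and both treatments in 1 model (-4.18), and ranged from -4.34 to -3.97 with each line or harvest left out.

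Without the divergent library, single-line counts in DMSO were 15 for sg2 and 5 for sg5 against the NTC mean, 2 between NTC lines, and medians of 5 for PURPL with NTC and 3.5 for PURPL with PURPL pairs; with Nutlin-3a they were 2, 8, 3, 3.5 and 1. MYBBP1A in PURPL lines with Nutlin-3a turned to -0.20 with the GC trend removed, -0.25 with the divergent library also left out and -0.20 with the GC trend removed and the pair block, the sterol isomerase gene EBP to -0.21 with both, and CDKN1A in DMSO to -0.18 without NTC2 (range to 0.23, without NTC1). Of 110 list results, 78 kept their side of the threshold with an estimated correlation and 32 became weaker, and with fry 81 kept it, 23 became weaker and 6 stronger. Genes far below 1 CPM rest on few counts, and how large a difference is detectable there was not tested.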

Other observations

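Long noncoding genes outside the fixed list also passed for Nutlin-3a, and the counts below include the long noncoding members of that list. Of 2016 long noncoding genes tested in the NTC lines, 136 rose and 24 fell in edgeR, of 13269 protein-coding genes 514 rose and 631 fell, and of 898 pseudogenes 26 rose and 2 fell. The difference between these classes was not tested. Nuclear-retained and mitochondrial transcripts of the RNA quality list rose in 5 of 12 cases in the same comparison (10 over the list alone), and the share of higher calls among all genes went from 50.9% to 35.8% without the divergent library. Of the long noncoding genes, 124 rose and 21 fell in both sets of lines. Examples at 1 CPM or more with Nutlin-3a, besides AL109976.1, were GAS6-AS1 (3.20), AL135905.1 (3.01), AL158206.1 (2.67) and LINC02086 (2.41), all log2, and MIR34AHG, the host transcript of the microRNA miR-34a, a known p53 target, had 2.16. AL158206.1 starts at 19453209 on chromosome 9, just past the end of ACER2 (19452020), which also rose. Whether its reads are separate from those of ACER2 was not tested. LINC00843 (-1.03) and AC125807.2 (-0.87) fell. Apart from AL109976.1, which the rule named, these genes were picked after their values were seen, and MIR34AHG is a member of the fixed list.

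CDH10 is a cadherin gene on the minus strand of chromosome 5 (24487100 to 24644978), with its lower coordinate 2.99 Mb from that of PURPL. It rose with Nutlin-3a by 3.20 in the NTC lines (edgeR adjusted p = 1.37e-08) and 3.03 in the PURPL lines (edgeR adjusted p = 1.57e-10) on the log2 scale. The guide comparisons gave 0.14 in DMSO and -0.05 with Nutlin-3a, neither past the threshold.

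The readings of the hypotheses in this part were set after some values had been seen. A different basal level of p53 targets in PURPL lines was not seen and not excluded. The mean log2 difference over 81 members of 3 p53 lists was -0.005 in DMSO (exact permutation p = 0.933), 0.014 with the GC trend removed and 0.015 with the divergent library also left out. The lines overlapped in each case, but a mean over members that go both ways does not rule out a small change. A different induction stays open too: the difference in response was 0.184 (exact permutation p = 0.267) with the NTC lines below all PURPL lines, and 0.098 (exact permutation p = 0.133) without the divergent library, where sg2 and NTC2 overlapped. With the GC trend removed it was 0.073, and 0.058 with the divergent library also left out, with the lines apart in both (exact permutation p = 0.0667, the smallest that 15 splits allow). A change shared by the PURPL guides also stays open. The covariance between guides set against different NTC lines was 0.0067 with Nutlin-3a and 2e-04 in DMSO. Simulated guides gave -1e-04 and 2e-04, but they were drawn independently. Their values near 0 were thus fixed in advance and give no bound for chance.

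With the divergent library left out, setting NTC1 and sg2 against the other lines called 4566 genes for the difference of responses, where the real split called 0 in edgeR, with 994 at an unadjusted p under 0.05. The sum of sg2 with Nutlin-3a held 1 library there, and what set these 2 lines apart was not tested. In DMSO the real split called 1 gene and so did 1 other split of 15.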
